A study of Homo sapiens with 6 samples.

How the data were processed

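The series measured gene expression in human pancreatic stellate cells, the fibroblast-like cells of the pancreas, on Illumina HT-12 v4 bead arrays. Per the labels, the cells came from surgical pancreatic tissue and were kept as 2 preparations, PSC1 and PSC2. Per the series title, they were separated by function in a modified Matrigel invasion assay, and each array held cells taken from the top side or from the bottom side. The 6 arrays formed 3 pairs of a top-side and a bottom-side sample: PSC1 with pancreatic cancer cells, PSC2 in monoculture, and PSC2 with pancreatic cancer cells. Per the labels' protocols, RNA was extracted with a column kit that includes a DNase step and was amplified and labelled with an Illumina kit. Per the series' design text, RNA quality was checked by automated electrophoresis and the arrays were read with BeadStudio 3.2.3.

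The values used were the deposited probe intensity values of the series' matrix of values, on a linear scale, for 47321 probes. The authors had scaled these intensity values by 1 factor per array, because each array had the same mean signal of 314.116 and the ratio to the non-normalized signal departed from its array's factor by at most 9.55e-07 in relative terms. The scaling was not described in the sources used here, and the values were not background-subtracted. A second deposited table gave non-normalized intensity and a detection p-value per probe and array. Of its 47315 rows, 15310 held these 6 arrays, and they were the probes detected on both PSC1 arrays. The remaining 32005 rows had no values for the last 2 samples, repeated 9695 probe identifiers with other values and were not used.

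Because the deposited detection p-values covered a filtered part of the probes, the planned neqc normalization of limma, which needs them for all probes, was not run. In its place the reported values used normexp background correction with an offset of 50, quantile normalization between arrays and log2, a setting listed before the data were examined. A probe counted as detected on an array when its intensity reached the lowest signal that had a detection p under 0.01 there. In 4 of the 4 arrays that could show it, detected and undetected signals did not overlap. Probes detected on at least 2 of 6 arrays were kept, which left 17804. Array depth was similar, with 16215 to 16885 probes detected per array (34.3% to 35.7%). The number of arrays limits the precision.

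Probes were named from the platform annotation. It gave 1 gene symbol for 30112 probes, several for 8 and none for 17201. The Entrez identifiers of 30073 named probes were found in a RefSeq gene listing, and 39 kept the annotation's symbol. Sex-linked genes (166 probes) were left out. Each gene was represented by its probe with the highest mean, giving 10763 genes, of which 2666 had more than 1 probe past the filter.

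Differences were tested with limma 3.58.1 in R 4.3.3 (files were read with version 1.17.8 of the data.table package), as lmFit and eBayes with pair and side as terms, 2 residual degrees of freedom, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The coculture comparison contrasted the PSC2 pairs in the same fit. The dependence of the bottom-to-top difference on coculture was an interaction term with 1 residual degree of freedom. Pairs came from the labels: both arrays of a pair carry the same preparation and culture. The deviations of same-numbered coculture samples from their group means correlated at 0.778 across genes, although groups of 2 give mirror-image deviations and so allow no second check. These deviations hold the difference between PSC1 and PSC2, so they cannot show that both arrays of a pair came from the same assay. The labels do not say whether the pairs came from separate experiments, so p-values measure only the spread between these samples, which may be technical. In this fit that spread is how the bottom-to-top difference varied between pairs. No spread between repeated cultures entered the SE or p-value of the coculture and preparation contrasts. With 3 pairs, an exact sign-flip test of a single gene cannot give a two-sided p below 0.25.

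There were 17 process lists and 5 lists of markers of other cell types, fixed before the data were examined. Lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry as alternatives. Of these lists, 1 was tested and is part of the adjustment and of the list counts, but it and its members named by the rule below are not reported here. Named genes also followed a rule fixed before the data were examined. It took the 12 largest rises and 12 largest falls between sides among genes with an adjusted p under 0.05 and the same direction in all 3 pairs. For the coculture comparison it took 10 and 10, with the same direction on both sides. It added up to 4 members per list with the largest change, and 12 genes that were always given. Genes differing between preparations were counted and not named, since a preparation may stand for 1 person.

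The steps were tested on simulated data with known changes in 10763 genes. For the side comparison, 51.8% of genes changed by 0.5 on the log2 scale and 99.2% of those changed by 1 were recovered, with 5.74% false calls. For the coculture comparison the shares were 17.0%, 95.6% and 5.70%. The simulated spread followed the variance model of the fit and held none between repeated cultures. These shares of false calls therefore leave out differences between culture runs. In the simulated list test, 20 of 20 shifted lists and 0 unshifted lists were called with the preset correlation, and 20 shifted lists with an estimated one. The simulated genes varied independently, so this test could not show false calls that arise from correlated genes. In the data the estimated correlation was 0.868 in the contractile list, 0.684 in the cell cycle list and 0.641 in the inflammatory list.

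Alternatives were quantile normalization without background correction, the authors' scaled values, no filter, detection on all 6 arrays, all probes, the mean of a gene's probes, eBayes with a trend or robust, no pair term, and each pair left out. Chosen after seeing the data were a normexp offset of 16, maximum-likelihood normexp, the probes of the non-normalized table alone, and the interaction of side with preparation. No slide or scan identifier was used here, so no slide term was fitted.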

Results

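Expression was measured on 6 arrays of human pancreatic stellate cells, which formed 3 pairs of cells from the top side and the bottom side of a modified Matrigel invasion assay. The pairs were PSC1 in coculture with pancreatic cancer cells, PSC2 in monoculture and PSC2 in coculture. PSC2 made up 2 of the 3 pairs, so SDs and p-values over 3 pairs rest on 2 preparations. The top-side and bottom-side coculture groups had 2 arrays each and the monoculture groups 1 each. Between 16215 and 16885 probes were detected per array, and 10763 genes were tested. All changes are on the log2 scale, and adjusted p-values are from limma.

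The first comparison asked which genes differed between cells taken from the 2 sides. The largest rises in bottom-side cells included smooth muscle and mitotic genes, and the largest falls included inflammatory cytokine genes. The largest rise was in ACTG2, the gamma actin of smooth muscle, at 1.74 ± 1.25 (SD, n = 3 pairs; adjusted p = 0.0225). The oxytocin receptor gene OXTR rose by 1.52 ± 0.48 (adjusted p = 0.00406), EDN1, which encodes an endothelin precursor, by 1.42 ± 0.57 (adjusted p = 0.00674), and the potassium channel subunit gene KCNMB1 by 1.41 ± 1.18 (adjusted p = 0.0336). KCNMB1 differed by 0.06 in the PSC1 pair and by 2.21 and 1.97 in the PSC2 monoculture and coculture pairs. The transcription factor gene NPAS1 rose by 1.25 ± 0.36, CNN1, a calponin of smooth muscle, by 1.23 ± 0.75, and the mitotic genes MELK, CDC20 and AURKB by 1.21 ± 0.63, 1.17 ± 0.46 and 1.08 ± 0.49. SHROOM3, AKAP12 and KIT completed the 12 largest rises, at 1.11 ± 0.51, 1.06 ± 0.23 and 1.05 ± 0.77.

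Cytokine and chemokine genes led the genes that were lower in bottom-side cells. IL1B had a difference of -2.16 ± 0.88 (SD, n = 3 pairs; adjusted p = 0.00598), the neutrophil chemokine genes CXCL8 and CXCL1 of -1.75 ± 0.80 and -1.72 ± 0.50, and IL6 of -1.64 ± 0.58 (adjusted p = 0.00502). IL33 fell in all 3 pairs, with a mean of -1.45 ± 0.25 (adjusted p = 0.00291). Also lower were PDK4, a kinase gene that restrains pyruvate oxidation (-1.73 ± 0.89), the nuclear receptor gene NR4A2 (-1.38 ± 1.07) and the stanniocalcin gene STC1 (-1.38 ± 0.72). ABCA8, C11orf96, SPRY1 and TMEM119 had differences of -1.30 ± 0.56, -1.29 ± 0.22, -1.28 ± 0.69 and -1.28 ± 0.25.

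**Figure D1:**
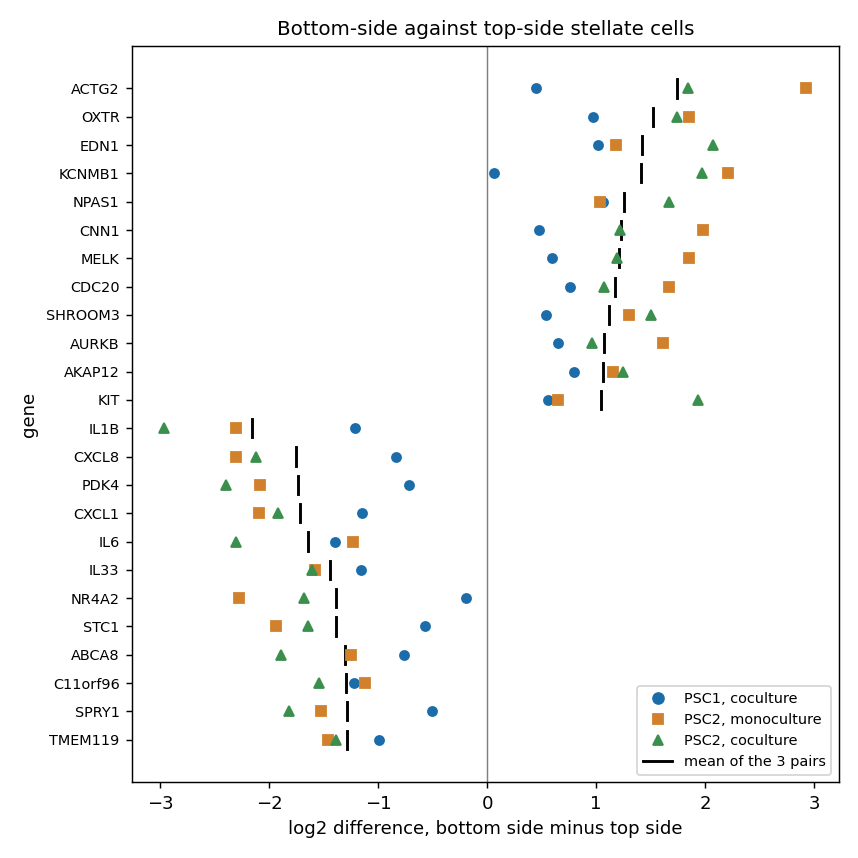
The log2 difference between bottom-side and top-side cells is plotted for the 12 genes with the largest rise and the 12 with the largest fall, with a point for each of the 3 pairs and a black line at their mean. All 3 points of each gene lie on the same side of 0, and for ACTG2 they range from 0.45 in PSC1 coculture to 2.93 in PSC2 monoculture.

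The 51 tested members of the cell cycle list were mostly higher in bottom-side cells. Of these, 36 rose, none fell and 15 did not pass, with 47 higher when adjusted over the list alone (median 0.61, camera adjusted p = 4.00e-30, adjusted p = 0.620 with an estimated correlation). TOP2A, a DNA topoisomerase gene, rose by 1.04 ± 0.50 and AURKA, a mitotic kinase gene, by 1.01 ± 0.49. The list's median was 0.34 in the PSC1 pair, 0.86 in PSC2 monoculture and 0.55 in PSC2 coculture.

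Of 15 tested contractile genes of myofibroblasts, 8 rose and none fell, with 11 higher when adjusted over the list alone (median 0.58, camera adjusted p = 3.72e-09, adjusted p = 0.620 with an estimated correlation). The myosin light chain gene MYL9 rose by 0.95 ± 0.64 and the kinase gene MYLK by 0.79 ± 0.52. ACTA2, the alpha actin used as a marker of activated stellate cells, had a difference of 0.58 ± 0.57 that did not pass (adjusted p = 0.0743), and it passed with the authors' scaling (adjusted p = 0.0464) and without the PSC1 pair (0.74, adjusted p = 0.00451). Without the PSC2 monoculture pair it was 0.25 (adjusted p = 0.380).

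Of 27 tested inflammatory cytokine and chemokine genes, 16 fell and none rose, with 20 lower when adjusted over the list alone (median -0.83, camera adjusted p = 1.05e-13, adjusted p = 0.620 with an estimated correlation). The chemokine gene CCL7 had a difference of -1.66 ± 1.66 that did not pass (adjusted p = 0.0548), and it was 0.16 in the PSC1 pair. It passed with the authors' scaling (adjusted p = 0.0436), with a variance trend (0.0445) and without the PSC1 pair (-2.57, adjusted p = 1.24e-07), and was -0.95 without the PSC2 monoculture pair (adjusted p = 0.212). Interferon response genes fell in 9 of 31 cases and none rose, with 12 lower and 1 higher when adjusted over the list alone (median -0.11, camera adjusted p = 0.00931, adjusted p = 0.620 with an estimated correlation). IFITM1, IRF1, UBE2L6 and GBP2 had differences of -0.96 ± 0.25, -0.83 ± 0.20, -0.63 ± 0.11 and -0.61 ± 0.18. This list no longer passed without the PSC1 pair (adjusted p = 0.241). Antioxidant and detoxification genes fell in 7 of 32 cases and none rose, with 8 lower when adjusted over the list alone (median -0.11, camera adjusted p = 0.00727, adjusted p = 0.620 with an estimated correlation). The heme oxygenase gene HMOX1 had a difference of -1.27 ± 0.32, the superoxide dismutase gene SOD2 of -1.19 ± 0.69 and the aldo-keto reductase genes AKR1C3 and AKR1C2, which are close in sequence, of -1.05 ± 0.49 and -0.86 ± 0.39.

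The following lists did not pass as a whole between sides in the reported setting, although single members did. In that setting 6 lists passed, against 7 without the filter on dim probes and 8 without the PSC2 coculture pair. Of 41 matrix genes, 5 rose and 1 fell, with 7 higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.952). Elastin (ELN) rose by 0.91 ± 0.57 and the cross-linking enzyme gene LOX by 0.69 ± 0.49, while COL7A1 had a difference of -0.82 ± 0.35. COL1A1 (0.02 ± 0.05), FN1 (0.16 ± 0.21) and VIM (0.34 ± 0.15) did not pass, although VIM passed with a variance trend (adjusted p = 0.0347) and without the PSC1 pair (0.41, adjusted p = 0.0140). Of 32 matrix protease genes, 2 rose and 6 fell, with 3 higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.475). The cathepsin genes CTSK and CTSL and the stromelysin gene MMP11 had differences of -0.74 ± 0.15, -0.58 ± 0.19 and -0.61 ± 0.25, and ADAM19 rose by 0.62 ± 0.46. MMP1 (0.14 ± 0.26), MMP2 (-0.26 ± 0.19) and MMP14 (0.10 ± 0.37) did not pass.

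In the TGF-beta list, 1 of 24 members rose and 5 fell (camera adjusted p = 0.914), among them PMEPA1 at -0.68 ± 0.04 and the oxidase gene NOX4 at -1.12 ± 0.30. Of 17 retinoid and lipid storage genes, 1 rose and 3 fell (camera adjusted p = 0.171), among them the lipid droplet gene PLIN2 at -1.07 ± 0.25. Of 36 growth factor genes, 2 rose and 6 fell (camera adjusted p = 0.375), with IGFBP2 at 0.80 ± 0.64, BMP2 at -0.84 ± 0.50 and VEGFA at -0.81 ± 0.67. When adjusted over the list alone, these 3 lists had 3 higher and 5 lower, 1 higher and 5 lower, and 5 higher and 10 lower. Camera adjusted p-values were 0.294 for integrins and matrix receptors, 0.191 for fibroblast and pericyte markers, 0.914 for hypoxia and glycolysis, 0.952 for cholesterol synthesis, 0.191 for protein and amino acid stress, and 0.597 for immediate early and heat shock genes. In this order, 2, 2, 1, 1, 1 and 3 members rose and 2, 2, 4, 1, 7 and 3 fell. Within these, the talin gene TLN1 rose by 0.61 ± 0.27, the pericyte proteoglycan gene CSPG4 by 0.95 ± 0.47 and KLF2 by 0.96 ± 0.58, while CEBPB, DDIT3, TRIB3 and ITGA10 had differences of -0.93 ± 0.28, -0.62 ± 0.22, -0.62 ± 0.23 and -0.56 ± 0.12. The median differed in sign from the mean or from the direction of the test for the matrix, TGF-beta, hypoxia and cholesterol lists, with medians of -0.06, 0.02, 0.02 and -0.03.

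**Figure D2:**
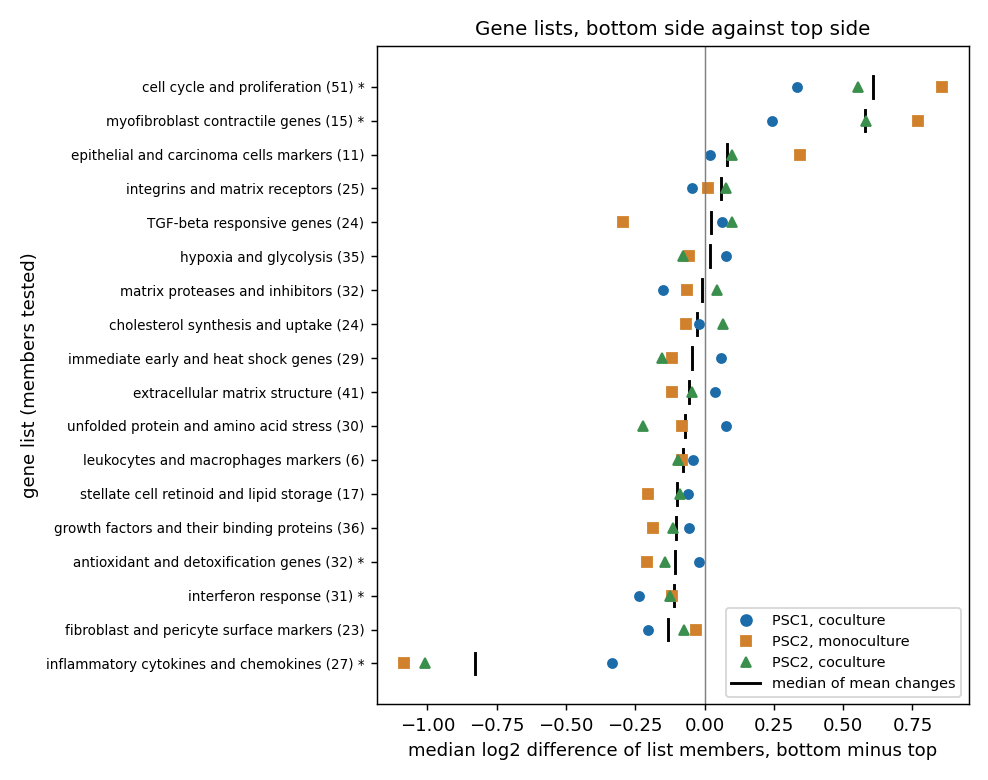
The median log2 difference between bottom-side and top-side cells is plotted for 18 gene lists, with a point per pair, a black line at the median of the members' mean changes, and an asterisk where the camera adjusted p was under 0.05. The cell cycle and contractile lists lie above 0 and the inflammatory list below 0 in all 3 pairs.

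Markers of other cell types were mostly below detection. Of 37 epithelial and carcinoma markers with a probe, 23 were detected on no array and 11 were tested, of which 3 rose and 1 fell between sides (camera adjusted p = 0.165). The keratin genes KRT7 and KRT19 rose by 0.94 ± 0.48 and 0.58 ± 0.12 and the desmosome gene DSP by 0.98 ± 0.34, while the junction gene JUP had a difference of -0.61 ± 0.11. The rises of KRT7, KRT19 and DSP in the PSC2 monoculture pair were 1.15, 0.57 and 0.96. EPCAM was detected on 1 array and was not tested. Of 6 tested leukocyte markers, CD14 alone passed (-0.52 ± 0.25, list camera adjusted p = 0.481). The endothelial, acinar and endocrine, and Schwann lists had 4, 3 and 4 tested members and were not tested as lists. Of their members, the endothelial gene VWF alone passed between sides (-0.48 ± 0.26, adjusted p = 0.0342). VWF lay near background, was not detected in PSC2 monoculture (mean log2 value 6.31) and had a mean of 6.24 in PSC2 coculture. The stellate cell markers DES and NGFR were detected on no array, and MME was detected on 1.

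In total 901 of 10763 genes passed between sides, 386 higher and 515 lower in bottom-side cells, and 899 of them had the same direction in all 3 pairs. Of these, 51 changed at least 2-fold, 18 higher and 33 lower. The count rested on the pairing and on the pairs included: it was 0 without the pair term (smallest adjusted p = 0.750), 0 without the PSC2 coculture pair (smallest adjusted p = 0.0594), 124 without the PSC2 monoculture pair and 2437 without the PSC1 pair. With the authors' scaled values the count was 990, with 327 higher and 663 lower. With robust variance estimates, 13 named values of both comparisons no longer passed. Between sides these were ACTG2, KCNMB1, CNN1, KIT and NR4A2 (adjusted p = 0.155, 0.197, 0.0629, 0.0917 and 0.172) and MYL9, ELN, LOX, ADAM19, VEGFA and IGFBP2 (0.0598, 0.0516, 0.0592, 0.0593, 0.0932 and 0.0884). KIT was 0.60 without the PSC2 coculture pair, and ACTG2, IGFBP2 and VEGFA were 1.14, 0.53 and -0.52 without the PSC2 monoculture pair. Another probe gave -0.54 for NOX4, -0.22 for CTSL, 0.38 for MYLK, -0.29 for UBE2L6, 0.64 for SHROOM3, 0.57 for DSP and, with a larger change, -2.03 for CXCL8.

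Without any variance model, 7 genes differed at least 2-fold in the same direction in all 3 pairs, against a mean of 0 for the mixed sign patterns. NPAS1 and EDN1 were higher in bottom-side cells, and IL6, IL1B, IL33, CXCL1 and C11orf96 were lower. At 1.5-fold, 55 genes met the criterion, 18 higher and 37 lower, against a mean of 0.333 for the mixed patterns. Most mixed patterns set the PSC2 pairs, which share a preparation, against each other. Their counts are therefore no baseline for independent pairs. Across genes, which are not independent replicates, the bottom-to-top differences of the PSC2 pairs in monoculture and coculture correlated at r = 0.736 (Spearman correlation 0.650). The PSC1 pair correlated with them at r = 0.399 (Spearman 0.344) and r = 0.447 (Spearman 0.377). The SD of the differences was 0.21 in PSC1, 0.34 in PSC2 monoculture and 0.34 in PSC2 coculture.

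The second comparison asked which genes differed in PSC2 between coculture with cancer cells and monoculture, with 2 arrays in each, from the top and the bottom side. TXNIP, which encodes a thioredoxin-binding protein, had the largest change, -4.08 ± 0.15 (SE, adjusted p = 3.74e-06), a 16.9-fold lower level in coculture. The pseudokinase gene TRIB3 differed by -1.85 ± 0.13, the serine synthesis gene PSAT1 by -1.71 ± 0.20, the asparagine synthetase gene ASNS by -1.55 ± 0.18, the transporter genes SLC7A5 and SLC3A2 by -1.46 ± 0.19 and -1.20 ± 0.14, and the mitochondrial folate enzyme gene MTHFD2 by -1.24 ± 0.14. PCK2, CBS and the quinone reductase gene NQO1 differed by -1.41 ± 0.14, -1.37 ± 0.14 and -1.19 ± 0.12. The 3 probes of PCK2 ranged from -1.41 to -0.20, and their mean gave -0.87.

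Higher in coculture were ID1 and ID3, inhibitors of basic helix-loop-helix transcription factors, at 1.71 ± 0.27 (SE, adjusted p = 0.0343) and 1.29 ± 0.22 (adjusted p = 0.0437), and IGFBP3 at 1.48 ± 0.17. ID1 and ID3 no longer passed with robust variance estimates (adjusted p = 0.173 and 0.146). The retinoid metabolism genes DHRS3 and CYP26B1 and the retinoid-responsive gene RARRES1 rose by 1.35 ± 0.13, 1.06 ± 0.11 and 1.02 ± 0.12. RASD2, FGL2, ENO2 and HSPA2 rose by 1.18 ± 0.16, 1.17 ± 0.13, 1.01 ± 0.13 and 1.00 ± 0.14.

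**Figure D3:**
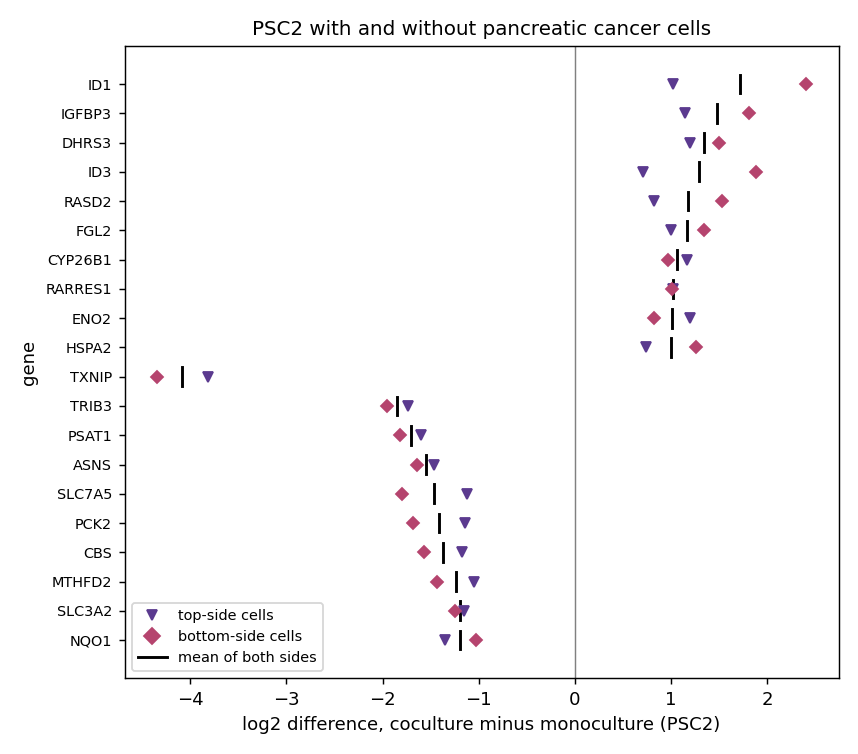
The log2 difference between coculture and monoculture of PSC2 is plotted for the 10 genes with the largest rise and the 10 with the largest fall, with a point for top-side and for bottom-side cells and a black line at their mean. TXNIP lies at -3.82 in top-side and -4.34 in bottom-side cells, apart from the other genes.

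Of 30 genes of protein and amino acid stress, 11 fell in coculture and none rose, with 18 lower and 1 higher when adjusted over the list alone (median -0.53, camera adjusted p = 2.62e-16, adjusted p = 0.245 with an estimated correlation). Of 32 antioxidant genes, 1 fell and none rose, with 8 lower when adjusted over the list alone (median -0.30, camera adjusted p = 2.45e-09, adjusted p = 0.245 with an estimated correlation). Hypoxia and glycolysis genes lay higher, with 1 of 35 passing and 19 higher and 1 lower when adjusted over the list alone (median 0.34, camera adjusted p = 8.54e-14, adjusted p = 0.245 with an estimated correlation). The glycolytic gene ALDOC had a difference of 0.68 ± 0.13 that did not pass (adjusted p = 0.0776).

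In the TGF-beta list, ID1 and ID3 rose out of 24 members, with 10 higher when adjusted over the list alone (median 0.29, camera adjusted p = 5.55e-07, adjusted p = 0.245 with an estimated correlation). Its members SMAD6 and ID2 differed by 1.09 ± 0.28 and 0.88 ± 0.23 and did not pass. Without the PSC1 pair, which enters this contrast through the variance alone, SMAD6, ID2 and ALDOC passed at the same values (adjusted p = 0.00623, 0.00439 and 0.00152). None of 41 matrix genes passed over all genes and 5 were higher when adjusted over the list alone (median 0.16, camera adjusted p = 1.02e-06, adjusted p = 0.245 with an estimated correlation). Of 17 retinoid and lipid storage genes, 3 rose, with 4 higher when adjusted over the list alone (median 0.09, camera adjusted p = 0.00292, adjusted p = 0.245 with an estimated correlation). The inflammatory list had 1 of 27 members lower, TNFAIP6 at -1.10 ± 0.13, with 4 lower and 1 higher when adjusted over the list alone (median -0.20, camera adjusted p = 7.14e-05, adjusted p = 0.539 with an estimated correlation).

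Camera also placed contractile genes (adjusted p = 6.14e-05, adjusted p = 0.531 with an estimated correlation), matrix proteases (0.000617, adjusted p = 0.245 with an estimated correlation), integrins (0.00524, adjusted p = 0.245 with an estimated correlation) and growth factors (0.0190, adjusted p = 0.245 with an estimated correlation) higher in coculture. None of 15 contractile and 32 protease genes passed, and 0 and 4 were higher when adjusted over the list alone. Of 25 integrin genes 1 rose, and of 36 growth factor genes 1 rose and 1 fell. In these lists the integrin gene ITGA1 rose by 0.84 ± 0.14, IGFBP3 rose as given above, and GDF15 had a difference of -0.65 ± 0.11. ITGA1 no longer passed without the filter (adjusted p = 0.0645), with the mean of probes (0.0593) or with a normexp offset of 16 (0.0628), and GDF15 with a variance trend (0.0603) or that offset (0.0698). Immediate early genes (adjusted p = 0.0147, adjusted p = 0.300 with an estimated correlation) were placed lower, with no member past the threshold over all genes. Cell cycle (adjusted p = 0.466), interferon (0.998), cholesterol (0.900), fibroblast marker (0.0559) and leukocyte marker (0.900) lists did not pass. The medians of the interferon and leukocyte lists were below 0 while the test placed both lists higher. Of the 11 epithelial markers, KRT19 rose by 0.85 ± 0.12 (adjusted p = 0.0180), with 3 higher when adjusted over the list alone (camera adjusted p = 0.0284, adjusted p = 0.259 with an estimated correlation). Without the filter on dim probes the growth factor and epithelial lists did not pass (adjusted p = 0.109 and 0.0659), nor did the epithelial list with the mean of probes (adjusted p = 0.0613). Without the pair term, which brought in the PSC1 arrays, the integrin and immediate early lists did not pass (adjusted p = 0.0736 and 0.136).

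In total 56 genes passed between coculture and monoculture, 26 higher and 30 lower, all with the same direction on both sides, and 25 changed at least 2-fold (10 higher, 15 lower). The count was 501 without the PSC1 pair, with 294 higher and 207 lower. Without the pair term it was 0 (smallest adjusted p = 0.0795), but the PSC1 coculture arrays then entered the comparison, which was no longer within PSC2. ACTA2 (0.33 ± 0.22), COL1A1 (0.14 ± 0.11) and MMP1 (-0.15 ± 0.14) did not pass. Each culture of PSC2 was a single run, so coculture and any other difference between the runs cannot be told apart.

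The third comparison asked whether the bottom-to-top difference depended on coculture. No gene passed the limma interaction test (smallest adjusted p = 0.147), and 348 had an unadjusted p under 0.05. With the authors' scaled values 27 genes passed, 14 with a higher and 13 with a lower bottom-to-top difference in coculture, and with a variance trend 1 gene passed. The test had 1 residual degree of freedom. It set the mean of the PSC1 and PSC2 coculture pairs against the PSC2 monoculture pair. Differences between the preparations entered both its effect and its spread. It therefore cannot show that the bottom-to-top difference was the same in both cultures.

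Between the preparations in coculture, 2029 genes (18.9%) differed, 937 higher and 1092 lower in PSC2 than in PSC1. No gene is named for this contrast. Each preparation had a single pair in coculture, so a difference between preparations and one between culture runs cannot be told apart.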

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

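The interaction of side with preparation, and the tests of carried-over carcinoma cells, array scaling, leukocytes, cancer cell effects, carcinoma RNA and culture runs, were chosen after the results were seen. The split count was planned before.

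The bottom-to-top difference of the PSC1 pair departed from that of the PSC2 pairs in 143 of 10763 genes in a limma interaction test (smallest adjusted p = 0.000208), with 69 differences higher and 74 lower in PSC1. Under the alternatives the count ranged from 15 with a normexp offset of 16 to 200 without the filter. It was 45 for the mean of probes, 64 for the probes of the non-normalized table and 99 for the authors' scaled values. Of these 99 differences, 70 were higher and 29 lower in PSC1. PSC1 was measured in coculture alone, so this test assumes that coculture left the difference between sides the same, and no gene is named because a preparation may stand for 1 person. PSC1 had 1 pair, so the preparation cannot be told apart from that pair or its run. The spread came from the PSC2 pairs alone, which differ in culture. In the non-normalized table, 32005 rows had no values for the last 2 samples and were not analysed here. Over the 9695 probes they repeated, they correlated with these arrays at no more than 0.847, and what they hold was not determined.

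For the count of genes differing between sides, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, reached 901 genes, and the highest other split gave 0. The 10 splits, 4 of which part all 3 pairs, are too few for a share under 0.05.

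In the cell cycle list, 36 of 51 genes were higher in bottom-side cells, although the list did not pass with an estimated correlation (adjusted p = 0.620). Carcinoma cells carried to the bottom side cannot account for the monoculture pair, which held none and had a list median of 0.86 (quartiles 0.62 and 1.25). In the signals before any scaling, genes of the same intensity outside the list had a median of -0.13 (upper quartile 0.000968). This lay below the lower quartile of 0.35 of the list. Scaling by 1 factor per array moves all genes alike and leaves this gap the same, so the comparison cannot test that scaling. It shows that the list stood apart from such genes before background correction and quantile normalization. Carcinoma cells in the coculture pairs stay open. The higher of KRT8 and KRT18 differed by 0.0340 between sides. KRT8 was detected on 2 and KRT18 on 3 of the 4 coculture arrays, so these values near background decide nothing. KRT7, KRT19 and DSP rose in all 3 pairs, by 1.15, 0.57 and 0.96 in the monoculture pair. Because that pair held no cancer cells, these rises cannot show carcinoma cells in the coculture pairs. JUP fell in all 3 pairs (-0.54 in PSC1 coculture, -0.73 in PSC2 monoculture and -0.55 in PSC2 coculture). A larger share of dividing cells on the bottom side stays a hypothesis that these arrays did not test.

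In the inflammatory list, 16 of 27 genes were lower in bottom-side cells, although the list did not pass with an estimated correlation (adjusted p = 0.620). A large share of leukocytes among the top-side cells is argued against by 5 abundant leukocyte genes (PTPRC, TYROBP, LAPTM5, FCER1G and LYZ). Of these, 0 were detected on any top-side array. A small share of leukocytes is not excluded by this. Of 21 markers in the fixed leukocyte list, 6 were detected on 2 or more arrays and 4 on all 6, and CD14 was lower in bottom-side cells. Cancer cells acting on or mixed with the stellate cells cannot account for the monoculture pair, where the list median was -1.08 (quartiles -1.61 and -0.66). A difference in state between stellate cells of the 2 sides stays open and was not tested further.

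In the list of protein and amino acid stress, 11 of 30 genes were lower in PSC2 coculture, although the list did not pass with an estimated correlation (adjusted p = 0.245). Carcinoma RNA diluting the stellate cell RNA would lower matrix genes as well, but the matrix list had a median of 0.16 (lower quartile 0.0410), against -0.53 for the stress list. A small share of carcinoma RNA is not excluded by this, and KRT19 rose by 0.85. A difference between 2 culture runs other than the cancer cells cannot be told apart from coculture, since there was 1 monoculture run of PSC2. The presence of cancer cells stays open for the same reason.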

How the results depend on the processing

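Alternatives chosen after seeing the data were the normexp offset of 16, maximum-likelihood normexp, the probes of the non-normalized table, and all those for the interaction with preparation. Except without the pair term or a pair, the side count ranged from 757 to 1000 and the coculture count from 43 to 61, and at least 693 and 42 of these genes were among those reported. Without the replicate block, 0 genes passed for side and 0 for coculture. The spread then came only from differences between PSC1 and PSC2 coculture arrays of the same side (2029 genes differed between these preparations). The PSC1 arrays also entered the coculture contrast, and no further cause was tested. Leaving out a pair moved the side count between 0 and 2437, the coculture count to 501, the preparation count to 1971, the side lists between 6 and 8 and the coculture lists to 14. For these the cause was not tested. Without the PSC1 pair, where the side and coculture counts rose, only PSC2 pairs were left. Their bottom-to-top differences correlated at r = 0.736. Without a pair the interaction has no residual degrees of freedom. With an estimated correlation 0 side and 0 coculture lists passed, and with fry 0 and 0. The count at 2-fold in all pairs was 55 at 1.5-fold and 13 with an offset of 16, which compresses dim probes less. The interaction with coculture gave 27 genes with the authors' values and 1 with a variance trend, and the cause was not tested. The interaction with preparation fell from 143 genes to 45 with the mean of a gene's probes, 15 with an offset of 16 and 64 with the probes of the non-normalized table, and the cause was not tested.

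Of the named values, 90 passed, and 81 of these passed under each alternative that tested them, other than robust variance, no block and left-out pairs. Of the 90, 84 could be tested when detection on all 6 arrays was required and 88 with the probes of the non-normalized table. The passed values outside the 81 were KCNMB1, LOX, ADAM19, VEGFA and IGFBP2 for side and ID1, ID3, ITGA1 and GDF15 for coculture. Robust variance kept 77, and 14 further named values passed without the PSC1 pair. Of the 66 passed side values, 41 passed without the PSC2 monoculture pair and 0 without the PSC2 coculture pair. Reversed signs, whose cause was not tested, were COL1A1 between sides (-0.00414) and FN1 with coculture (-0.0302) with the authors' values, and FN1 (-0.00823) with the mean of probes. Without the block, coculture values reversed for RASD2 (-0.0553), FGL2 (-0.44), GDF15 (0.54), FN1 (-0.0666), MMP1 (2.07) and MMP2 (-0.0553). Without a pair, MMP1 ranged from -0.00503 to 0.231 and MMP14 from -0.0451 to 0.308 between sides, both lowest and reversed without the PSC2 coculture pair. neqc and a slide term were not run. Signals near the detection threshold limit dim genes.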

Other observations

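Within the cell cycle list, genes of DNA replication and genes of mitosis were both higher in bottom-side cells. Of 18 tested genes of DNA replication and its start, 12 rose (median 0.52), and of 33 tested genes of G2 phase and mitosis, 24 rose (median 0.65). In PSC2 monoculture the medians were 0.75 and 1.07, and in PSC1 coculture 0.34 and 0.34. This division of the list was made after its values were seen.

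The following 4 hypotheses came from genes described above. Each was tested on a further list of genes or, for the last, on a single further gene. The outcome that would count against each was written before. Lower FOXO activity in bottom-side cells may accompany the lower PDK4. Of 16 tested FOXO-responsive genes, of which BNIP3L was also in the hypoxia list, 4 fell and none rose over all genes, and when adjusted over the list alone 7 were lower and 1 higher. The median was -0.26 (camera p = 0.00467, but p = 0.320 with an estimated correlation), and -0.27 without BNIP3L. The medians of the single pairs ranged from -0.376 to -0.059. BCL6 (-0.73 ± 0.31, SD of 3 pairs) and IRS2 (-0.48 ± 0.14) were among those that fell, and GADD45A went the other way (0.52 ± 0.40, adjusted p = 0.0520).

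Higher activity of SRF and its MRTF cofactors, which drive actin genes, may accompany the contractile genes. Of 16 tested targets outside the contractile list, of which CCN1 and CCN2 were also in the TGF-beta list, 4 rose and none fell over all genes, and 11 were higher when adjusted over the list alone. The median was 0.39 (camera p = 7.01e-07, but p = 0.254 with an estimated correlation), and 0.38 without CCN1 and CCN2. The medians of the single pairs ranged from 0.098 to 0.597. NEXN rose by 0.76 ± 0.53 and TPM4 by 0.45 ± 0.07. The largest rise was in ANKRD1, at 1.29 ± 1.19 (adjusted p = 0.0449), with a wide spread between pairs.

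Lower ATF4 activity in coculture may underlie the fall of amino acid stress genes. Of 14 tested synthetase, transporter and enzyme genes outside that list, 12 were lower, none passed over all genes, and 9 were lower and 1 higher when adjusted over the list alone. The median was -0.39 (camera p = 6.63e-08, but p = 0.0830 with an estimated correlation). SLC38A2, also an ATF4 target, had a difference of 0.45 ± 0.11 (SE) in the other direction.

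Lower glucose sensing through MondoA, which controls TXNIP together with ARRDC4, may account for the fall of TXNIP. ARRDC4 changed by -0.26 ± 0.11 (SE, adjusted p = 0.393), with -0.25 in top-side and -0.28 in bottom-side cells, against -4.08 for TXNIP. The fall of at least 1 on the log2 scale that this hypothesis required was not seen. How far ARRDC4 lay above background did not enter this test, and a dim gene could not show such a fall.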
